A study of Mus musculus with 6 samples.

How the data were processed

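RNA-seq was run on 6 libraries of mouse bone marrow cells, 2 each from day 0, day 4 and day 7 of an ex vivo culture with Flt3 ligand. Per the labels' protocols, total RNA was isolated with Qiagen RNeasy columns, and libraries were made with SMARTer v3 Ultra Low Input and NexteraXT kits. The deposited table gives RPKM, reads scaled by exon length and library total, for 21761 genes with their Entrez IDs, symbols and lengths, per the file headers. The genome build mm9, TopHat2 2.0.13 and SAMtools 1.1 are named without roles, per the submitters' processing notes. The read counter, the gene annotation and any handling of strand are not given in the sources used here. Without strand, reads of a gene and of an overlapping antisense gene cannot be separated. No coordinates are given, because the annotation used here is of another build than mm9.

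RPKM times gene length added up to the same total in each library, and every value was a whole multiple of the worth of 1 read. The largest distance from a whole read was 1.10e-06 to 6.80e-05 reads over the 6 libraries, so reads and library totals were read back. Totals ran from 157797 to 16149088 reads, and the floor of 3 reads of a gene 1 kb long ran from 0.186 to 19.01 RPKM. Exact Clopper-Pearson intervals at 95% were computed for shares of reads. Symbols were missing for 92 entries of the table and none of these could be given one by Entrez ID. Genes of odorant, vomeronasal and trace amine receptors were taken by symbol.

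Values were used as log2(RPKM + 1), so that fold changes understate the change of genes with low values. Genes with RPKM of at least 1 in at least 2 of the 6 libraries were tested, 19279 in all. A model of 3 group means was fitted to the 6 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend), leaving 3 residual degrees of freedom and a median of 5.22 prior ones. Groups were compared as day 4 against day 0, day 7 against day 4 and day 7 against day 0. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested in a comparison, and a gene was called at adjusted p under 0.05. With 2 libraries in each group an exact permutation of labels could not pass that threshold, and limma was used for every p of a gene. Genes highest or lowest at day 4 were those called in opposite directions in the 2 steps, and their number was set beside that of independent lists and of 20 simulated draws without change, from which as many genes per step and direction were taken by smallest p. Files were read with the data.table package (version 1.17.8), the replicate correlation used statmod 1.5.0, and plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

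The groups, comparisons, tests, 34 gene lists, alternative settings and the rule for naming genes were fixed before the data were examined. The lists covered plasmacytoid, conventional, type 1 and type 2 conventional DCs, DC transcription factors and maturation, MHC classes I and II, innate sensors, interferon-stimulated genes and cytokine receptors. They also covered stem and early progenitors, myeloid progenitors, neutrophils, monocytes and macrophages, erythroid, B lineage, plasma, T and NK cells, basophils and mast cells, eosinophils, megakaryocytes, and stromal and endothelial cells. The others held S phase, mitosis, ribosomal proteins, lysosome, cholesterol synthesis, glycolysis, oxidative phosphorylation, nuclear architecture, DNA methylation, immediate early genes and p53 targets. Of 680 entries 675 were found in the table. Hba-a1 was allowed by the naming rule, and no value for it was used here. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation. Benjamini-Hochberg adjustment was over the 34 lists. With an estimated correlation camera rests on the 3 residual degrees of freedom and has little power. For the erythroid list at day 4 against day 0 the estimate was 0.00457, below the preset, yet adjusted p went from 5.82e-16 to 0.1. A call lost there is thus by itself no sign of correlated members. Camera sets a list against other genes, while fry, an alternative, tests whether members move one way on balance.

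The rule for naming genes allowed, per comparison, the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among called genes with a mean of at least 5 RPKM and both libraries of one group above both of the other. Symbols that start with Mir, Snor, Scarna, Rnu or n-R, predicted genes, clone names, gene segments and entries without a symbol were skipped. Other RNA genes, such as Rpph1, were not skipped. A subset was taken in rank order. It also allowed, for each list, up to 4 tested members with the highest mean RPKM and up to 2 with the smallest adjusted p, and a set of cell type genes fixed by name, among them Flt3, Itgax, Zbtb46, Siglech, Mpo and Xist. For genes highest or lowest at day 4 it allowed the 10 with the largest smaller change in each direction. Genes with no reads in either library of a group were given no fitted fold, and their bound was taken against the higher of the 2 libraries' floors of 3 reads.

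Alternative settings fixed then were pseudocounts of 0.1 and 5, no filter and a filter of 5 RPKM, scaling to median ratios, to common quantiles or to a common total, fits of only the groups compared, no trend, weights per library, robust eBayes, the replicate numeral as a random effect, a log2 threshold of 1, leaving out each library, camera with an estimated correlation, fry, and lists without shared members. Alternatives chosen after seeing the data were voom on the reads read back, subtraction of the receptor gene background, thinning to 157797 reads, and a filter of 20 RPKM in 2 libraries.

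The fit was tested on simulated reads for the real genes and library sizes, with a single spread per group taken from well covered genes. Unchanged genes had the same mean in all groups, so the receptor gene background of day 0 and day 4 was not simulated. Changed genes were drawn only from those with a mean of at least 5 RPKM and were spread over fold sizes of 4 and 16. With 200 changed genes, limma recovered 0% of 4-fold and 29.0% of 16-fold changes for day 4 against day 0, 0% and 0% for day 7 against day 4 (81.0% and 96.0% at unadjusted p under 0.05), and 4.00% and 26.0% for day 7 against day 0. Unchanged genes called were 26, 0 and 19. With 4000 changed genes it recovered 46.6% and 87.1%, 34.7% and 86.7%, and 49.0% and 87.8% in the same order, and called 1163, 49 and 1347 unchanged genes. At day 4 against day 0, 4-fold rises (2.00 on the log2 scale) were estimated at a median of 2.08 and 4-fold falls at -1.57, where the pseudocount shrinks low values.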

Results

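Gene expression was measured by RNA-seq in mouse bone marrow cells at 3 points of an ex vivo culture with Flt3 ligand (Flt3L), the cytokine that drives dendritic cell (DC) development from marrow progenitors. Per the labels, the cells came from male C57BL/6J marrow and were grown with a supernatant that contained Flt3L. The 6 libraries fell into 3 groups of 2: fresh marrow at day 0 (replicates II and III), cells at day 4 (replicates I and II, titled CMP by the submitters) and cells at day 7 (replicates III and IV, titled BMDC). Nothing in the labels says that replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

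Depth differed by day of culture. The day 0 libraries II and III held 322837 and 157797 reads in genes, the day 4 libraries I and II 1365635 and 3852628, and the day 7 libraries III and IV 16149088 and 10951745. A single read of a gene 1 kb long was therefore worth 3.10 and 6.34 RPKM at day 0, 0.732 and 0.260 RPKM at day 4, and 0.0619 and 0.0913 RPKM at day 7. A floor of 3 reads of such a gene stood at 9.29 and 19.01 RPKM in the day 0 libraries, so lower expression was not reliably detectable there. Of 21761 genes, 18534 and 16964 had reads at day 0, 20629 and 19777 at day 4, and 13658 and 12278 at day 7.

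Reads in genes of odorant, vomeronasal and trace amine receptors, sensory receptors of the olfactory system, were counted as a background measure. These 1449 genes took 1.51% (exact Clopper-Pearson 95% interval 1.47 to 1.55) and 1.44% (1.38 to 1.495) of reads at day 0, and 0.749% (0.735 to 0.764) and 0.147% (0.143 to 0.150) at day 4. The day 7 shares were 0.00378% (0.00348 to 0.00409) and 0.00409% (0.00372 to 0.00449). Intervals and floors cover counting error only, because PCR copies are not independent molecules.

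**Figure D1:**
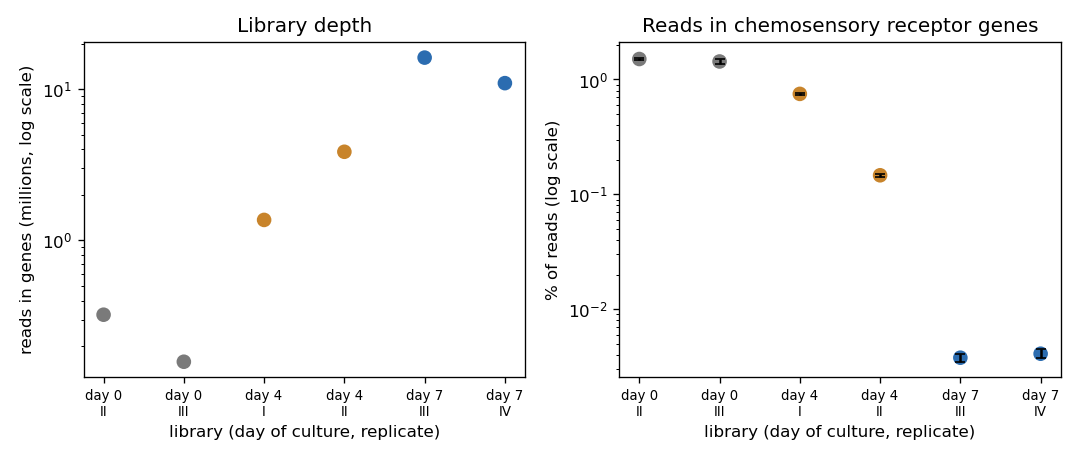
Reads in genes (left, log scale) and percent of reads in chemosensory receptor genes (right, log scale) in each of the 6 libraries, with exact 95% binomial intervals as error bars on the right. The day 0 libraries had the fewest reads, 322837 and 157797, and the highest receptor shares, 1.51% and 1.44%.

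Libraries of one day lay nearest each other at day 4 and day 7. The Pearson correlation of log2(RPKM + 1) across genes was 0.562 between the day 0 libraries, 0.899 between the day 4 libraries and 0.976 between the day 7 libraries. Day 0 library II correlated at 0.666 and 0.676 with the day 4 libraries, above its correlation with day 0 library III. The first principal component held 60.8% of the variance, with both day 7 libraries (147 and 157) on one side and both day 0 libraries (-100.1 and -152) on the other. Between replicates, 38.3% of tested genes differed by over 2-fold at day 0, 37.0% at day 4 and 6.48% at day 7. The limma fit assumed a single spread per gene over the days, although these shares differ. The p of a gene for day 4 against day 0 thus drew in part on the smaller spread at day 7.

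**Figure D2:**
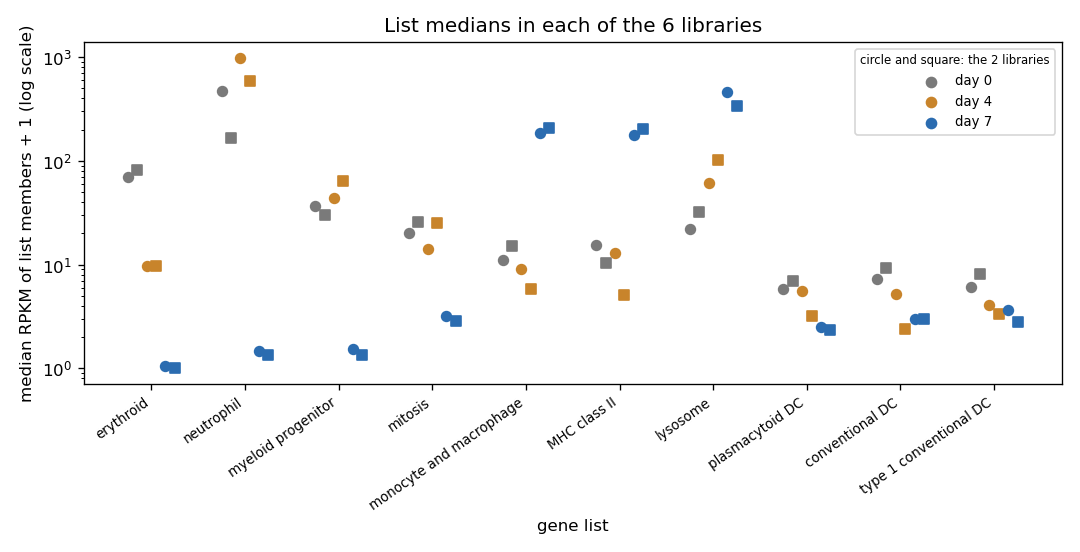
Median RPKM + 1 (log scale) over the members of 10 gene lists in each of the 6 libraries, circle and square marking the 2 libraries of a day. The neutrophil medians were 984 and 583 RPKM at day 4 against 0.480 and 0.333 RPKM at day 7, and the monocyte and macrophage medians 8.14 and 4.76 RPKM against 185 and 206 RPKM.

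Day 4 was compared with day 0 to follow the first part of the culture. Whether the cells titled CMP and BMDC were sorted is not clear from the labels. Here and below, selection of cells therefore cannot be told apart from change in culture. Red cell genes were among those that fell. Hbb-b1, which encodes a beta globin chain, fell from 24774 ± 8519 RPKM at day 0 to 1617 ± 91.2 RPKM at day 4 (mean ± SD, n = 2 libraries per group here and below), a log2 fold change of -3.89 ± 0.61 (± SE here and below, limma adjusted p = 0.0166). Hba-a2, an alpha globin gene, fell from 33299 ± 19476 to 2115 ± 95.2 RPKM (-3.84 ± 0.79, adjusted p = 0.0332). Among genes with a mean of at least 5 RPKM and reads on both days the largest called fall was that of Car1, a carbonic anhydrase abundant in red cell precursors, at 216 ± 86.2 and 1.33 ± 0.486 RPKM (-6.49 ± 0.47, adjusted p = 0.00544). It was followed by Lars2, a mitochondrial leucyl-tRNA synthetase (-5.47 ± 0.62, adjusted p = 0.00721), and Aqp1, the water channel of the red cell membrane (-5.07 ± 0.52, adjusted p = 0.00721). Slc4a1, the anion exchanger of that membrane, fell from 384 ± 155 to 18.8 ± 0.467 RPKM (-4.22 ± 0.41, adjusted p = 0.00711). Of the 22 tested members of the erythroid list 20 fell and 0 rose (22 fell when adjusted over the list alone), and the list lay below other genes (camera adjusted p = 5.82e-16, or adjusted p = 0.1 with an estimated correlation). Its median was 69.02 and 80.4 RPKM in the day 0 libraries and 8.76 and 8.76 RPKM in the day 4 libraries. Near-identical globin genes can share reads, so the split of reads among the globin copies is uncertain.

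Genes of the lysosome and of glycolysis were among those that rose. Ctsd, a lysosomal aspartic protease, rose from 100.8 ± 51.1 to 1962 ± 567 RPKM (4.34 ± 0.70, adjusted p = 0.0178) and Lipa, the lysosomal acid lipase, from 5.06 ± 4.24 to 84.4 ± 22.4 RPKM (3.995 ± 0.54, adjusted p = 0.012). Neu1, a lysosomal sialidase, rose from 7.296 ± 3.34 to 78.7 ± 30.4 RPKM (3.27 ± 0.44, adjusted p = 0.012). 10 of 21 lysosome genes rose (13 when adjusted over the list alone) and 0 fell. Lysosome genes gave camera adjusted p = 9.71e-13, and adjusted p = 0.253 with an estimated correlation. The list medians were 20.9 and 31.1 RPKM at day 0 and 59.99 and 101.2 RPKM at day 4. In glycolysis 5 of 13 genes rose (9 when adjusted over the list alone). Glycolysis genes gave camera adjusted p = 4.46e-07, and adjusted p = 0.396 with an estimated correlation, and their call was lost in 2 of 23 alternatives, with adjusted p = 0.0755 by fry. Aldoa, the aldolase, rose from 207 ± 161 to 1925 ± 188 RPKM (3.46 ± 0.72, adjusted p = 0.0349) and Pkm, pyruvate kinase, from 214 ± 102 to 1634 ± 610.2 RPKM (2.96 ± 0.61, adjusted p = 0.0342), while Gapdh stood at 355 ± 437 and 574 ± 158 RPKM (adjusted p = 0.346).

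Some targets of p53 and enzymes of sterol synthesis rose. Bax, a pro-apoptotic gene, rose from 10.97 ± 2.93 to 134 ± 64.1 RPKM (3.43 ± 0.45, adjusted p = 0.0117) and Mdm2, the ubiquitin ligase that restrains p53, from 12.98 ± 10.03 to 109 ± 62.2 RPKM (3.07 ± 0.62, adjusted p = 0.0314). Cdkn1a, which encodes the cell cycle inhibitor p21, did not pass at 4.16 ± 4.24 and 17.8 ± 2.98 RPKM (adjusted p = 0.0712). 4 of 12 p53 targets rose (7 when adjusted over the list alone). Targets of p53 gave camera adjusted p = 8.84e-06, and adjusted p = 0.248 with an estimated correlation. Of 20 cholesterol synthesis genes 3 rose (8 when adjusted over the list alone). Cholesterol synthesis genes gave camera adjusted p = 8.84e-06, and adjusted p = 0.253 with an estimated correlation, and their call was lost in 2 of 23 alternatives, with adjusted p = 0.0755 by fry. Msmo1, a sterol demethylase, rose from 3.94 ± 1.801 to 33.5 ± 2.47 RPKM (2.85 ± 0.41, adjusted p = 0.0127).

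Granulocyte genes were abundant at both times. Ngp, a neutrophil granule gene, had 11154 ± 12486 RPKM at day 0 and 13081 ± 2292 RPKM at day 4 (adjusted p = 0.566), and S100a8, a calcium-binding protein of neutrophils and monocytes, 11256 ± 12511 and 8683 ± 2243 RPKM (adjusted p = 0.892). 4 of 19 neutrophil genes rose (5 when adjusted over the list alone). Neutrophil genes gave camera adjusted p = 9.67e-06, and adjusted p = 0.618 with an estimated correlation, and their call was lost in 4 of 23 alternatives, with adjusted p = 0.244 without day 0 library III, 0.254 at 20 RPKM and 0.214 by fry. Padi4, an enzyme that citrullinates histones in neutrophils, rose from 18.9 ± 11.1 to 159 ± 24.2 RPKM (3.12 ± 0.47, adjusted p = 0.0153). In the basophil and mast list 2 of 12 rose (3 when adjusted over the list alone). Basophil and mast cell genes gave camera adjusted p = 0.0358, and adjusted p = 0.396 with an estimated correlation, and their call was lost in 8 of 22 alternatives, with adjusted p = 0.0882 without day 0 library II and 0.214 without day 4 library II. The pair that rose was the basophil protease gene Prss34, at 15.3 ± 21.6 and 336 ± 146 RPKM (5.83 ± 1.33, adjusted p = 0.0455), and Hdc, which makes histamine, at 77.5 ± 30.4 and 331 ± 112 RPKM (2.09 ± 0.43, adjusted p = 0.0338). Cytokine receptors had 4 of 22 genes higher and 1 lower (9 and 1 when adjusted over the list alone). Cytokine receptors gave camera adjusted p = 0.0242, and adjusted p = 0.621 with an estimated correlation, and their call was lost in 8 of 23 alternatives, with adjusted p = 0.183 under quantile normalization, 0.135 without day 0 library II and 0.117 without day 4 library II. Csf2ra, a subunit of the GM-CSF receptor, rose from 55.2 ± 14.1 to 248 ± 27.03 RPKM (2.17 ± 0.40, adjusted p = 0.0247). Innate sensors had 2 of 23 higher (6 higher and 3 lower when adjusted over the list alone). Innate sensors gave camera adjusted p = 0.027, and adjusted p = 0.396 with an estimated correlation, and their call was lost in 7 of 23 alternatives, with adjusted p = 0.112 without day 0 library II and 0.104 without day 4 library II. Those that rose were Tlr13, a sensor of bacterial RNA (3.01 ± 0.38, adjusted p = 0.011), and Unc93b1, which carries Toll-like receptors to endosomes (1.68 ± 0.39, adjusted p = 0.0462).

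Other large rises were those of Cstb, an inhibitor of cathepsins (5.92 ± 1.17, adjusted p = 0.0299), Rnf128, a ubiquitin ligase (5.49 ± 0.45, adjusted p = 0.00544, with 1 read at day 0 and a ratio of pooled depth-scaled reads of 92.2, exact 95% interval 16.5 to 3650), and Slc7a11, a cystine transporter (5.45 ± 0.51, adjusted p = 0.00711). In the S phase list 3 of 20 genes fell (7 when adjusted over the list alone). S phase genes gave camera adjusted p = 0.000326, and adjusted p = 0.487 with an estimated correlation, and their call was lost in 4 of 23 alternatives, with adjusted p = 0.238 without day 4 library I, 0.0598 after thinning and 0.0755 by fry. Tyms, thymidylate synthase, fell from 288 ± 96.7 to 24.8 ± 17.4 RPKM (-3.63 ± 0.54, adjusted p = 0.0139) and Mcm2, a replicative helicase subunit, from 88.5 ± 26.4 to 9.92 ± 3.28 RPKM (-3.04 ± 0.42, adjusted p = 0.012). Limma called 0 of 23 oxidative phosphorylation genes over all genes and 0 when adjusted over the list alone (1 was higher at unadjusted p under 0.05), although the list was called higher (camera adjusted p = 0.0156, or adjusted p = 0.757 with an estimated correlation, the call being lost in 8 of 23 alternatives, with adjusted p = 0.923 under quantile normalization, 0.97 without day 0 library III and 0.26 without day 4 library II). That call ended with its direction turned under quantile normalization, where the list median of 0.51 became 0.17 relative to an all-gene median of -0.04, and without day 0 library III, where it became -0.07.

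Flt3, Zbtb46 and Siglech, genes of dendritic cells, did not pass the test. Flt3, the receptor for Flt3L, had 12.1 ± 7.46 and 3.66 ± 2.76 RPKM (adjusted p = 0.196), Zbtb46, a transcription factor of conventional DCs, 3.65 ± 1.77 and 1.85 ± 2.04 RPKM (adjusted p = 0.482), and Siglech, a lectin of plasmacytoid DCs, 1.45 ± 2.05 and 6.91 ± 5.76 RPKM (adjusted p = 0.209). Limma called 0 of 20 plasmacytoid DC genes (1 higher and 2 lower when adjusted over the list alone, 2 and 4 at unadjusted p under 0.05). Plasmacytoid DC genes gave camera adjusted p = 0.924, and adjusted p = 0.964 with an estimated correlation. Of 29 conventional DC genes 0 rose and 2 fell (3 and 3 when adjusted over the list alone). Conventional DC genes gave camera adjusted p = 0.404, and adjusted p = 0.831 with an estimated correlation. The falling pair was Ap1s3, an adaptor subunit (-4.08 ± 0.66, adjusted p = 0.018), and Ass1, of arginine synthesis (-2.58 ± 0.49, adjusted p = 0.0278). The type 1 conventional DC list was called lower (camera adjusted p = 0.0358, or adjusted p = 0.673 with an estimated correlation, the call being lost in 11 of 23 alternatives, with adjusted p = 0.079 under quantile normalization, 0.157 without day 0 library II and 0.0557 without day 4 library I) with 0 of 16 members called by limma over all genes and 0 when adjusted over the list alone (0 were higher and 5 lower at unadjusted p under 0.05). Cd24a, its most abundant member at day 0, stood at 442 ± 1 and 224 ± 0.846 RPKM (adjusted p = 0.201). Monocyte and macrophage genes went both ways, 1 of 20 higher and 4 lower (3 and 6 when adjusted over the list alone). Monocyte and macrophage genes gave camera adjusted p = 0.484, and adjusted p = 0.825 with an estimated correlation.

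Of 19279 genes tested for day 4 against day 0, limma called 705 higher and 370 lower at adjusted p under 0.05 (65.6% higher). The split was 116 and 193 (37.5% higher) with voom on recovered reads, 449 and 1209 (27.1%) after thinning all libraries to the smallest, and 423 and 112 (79.1%) with a pseudocount of 0.1. Camera called 9 of 34 lists higher and 3 lower, of which 0 passed with an estimated correlation (4 of 34 at unadjusted p under 0.05). That form has little power with 3 residual degrees of freedom. In 2 lists, type 2 conventional DC and DC maturation, the median or the mean differed in sign from the test. The median log2 fold change of all genes was -0.40, and -0.42, -0.29 and -0.04 after scaling to a common total, to median ratios and to common quantiles. Of the genes named in the text 43 passed in this comparison, and all of these had both libraries of one day above both of the other. The naming rule required this of some of them, so it is no separate support for the calls. Receptor genes were 34 of the 370 lower genes and 5 of the 705 higher ones. Without day 4 library I or II limma called 0 genes (6499 and 3437 at unadjusted p under 0.05), without day 0 library II 2397, and without day 7 library III or IV 505 and 508, while weights per library also left 0 calls (2757 at unadjusted p under 0.05). In simulated data with 4000 changed genes 30.3% of the calls fell on unchanged genes, 1163 in number. Of these 72 were called lower and the others higher, and 104 had a mean of at least 5 RPKM. Changed genes were drawn only from that mean upward, so every call below it fell on an unchanged gene. The share is therefore no error rate for the real calls. With 200 changed genes the share was 47.3%, and 23 of the unchanged genes called had a mean of at least 5 RPKM.

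Day 7 was compared with day 4 to follow the second part of the culture. Macrophage genes were among those that rose. C1qb, a chain of complement component C1q, rose from 2.88 ± 3.73 RPKM at day 4 to 1723 ± 127 RPKM at day 7 (9.24 ± 0.72, adjusted p = 0.000325). C1qc, another C1q chain, rose from 1.98 ± 2.11 to 1090.2 ± 83.7 RPKM (8.72 ± 0.86, adjusted p = 0.000798) and Cd5l, a secreted macrophage protein, from 1.96 ± 0.788 to 958 ± 7.79 RPKM (8.37 ± 0.37, adjusted p = 0.000106). Trem2, a lipid-sensing receptor of macrophages, rose from 2.94 ± 0.262 to 1155 ± 45.9 RPKM (8.20 ± 0.64, adjusted p = 0.000327), and Apoe, a lipid carrier, from 20.8 ± 0.279 to 4762 ± 45.9 RPKM (7.77 ± 0.50, adjusted p = 0.0002). Csf1r, the receptor for the macrophage growth factor M-CSF, rose from 16.6 ± 6.85 to 230.4 ± 15.7 RPKM (3.77 ± 0.42, adjusted p = 0.00128). Ly6c2, a marker of inflammatory monocytes, fell from 1014 ± 239 to 48.3 ± 1.61 RPKM (-4.34 ± 0.56, adjusted p = 0.00251), and Lyz2, lysozyme, stood at 6253 ± 1204 and 6748 ± 673 RPKM (adjusted p = 0.941). Of the 20 monocyte and macrophage genes 12 rose and 2 fell (14 and 3 when adjusted over the list alone). Monocyte and macrophage genes gave camera adjusted p = 3.01e-12, and adjusted p = 0.263 with an estimated correlation.

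Some genes of antigen presentation also rose. Cd74, the MHC class II invariant chain, rose from 115 ± 117 to 1873 ± 83.3 RPKM (4.53 ± 0.81, adjusted p = 0.0104) and H2-Ab1, a class II chain, from 31.9 ± 29.4 to 698 ± 45.3 RPKM (4.78 ± 0.76, adjusted p = 0.00619). H2-Eb1, another class II chain, rose from 2.84 ± 2.33 to 302 ± 16.7 RPKM (6.45 ± 0.47, adjusted p = 0.000297) and Ctss, the protease that trims the invariant chain, from 44.9 ± 19.7 to 3949.6 ± 152 RPKM (6.50 ± 0.47, adjusted p = 0.000279). Ciita, the class II transactivator, was at 1.4 ± 1.37 and 0.617 ± 0.442 RPKM (adjusted p = 0.599). 9 of 14 class II genes rose (9 when adjusted over the list alone) and 0 fell. MHC class II genes gave camera adjusted p = 5.04e-10, and adjusted p = 0.356 with an estimated correlation. The list medians were 12.03 and 4.12 RPKM at day 4 and 176 and 202 RPKM at day 7. MHC class I had 3 of 13 genes higher (3 when adjusted over the list alone). MHC class I genes gave camera adjusted p = 0.0129, and adjusted p = 0.286 with an estimated correlation, and their call was lost in 6 of 23 alternatives, with adjusted p = 0.629 under quantile normalization. B2m, the light chain of class I molecules, rose from 292 ± 22.7 to 1935 ± 29.1 RPKM (2.73 ± 0.62, adjusted p = 0.0255), and the heavy chain gene H2-D1 stood at 2306 ± 822 and 2186 ± 14.2 RPKM (adjusted p = 0.98).

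Many granulocyte genes fell. Ngp fell from 13081 ± 2292 to 0.594 ± 0.161 RPKM (-12.99 ± 0.93, adjusted p = 0.000274) and Ltf, lactoferrin, from 4216 ± 275 to 0.381 ± 0.0679 RPKM (-11.58 ± 0.57, adjusted p = 0.000106). Camp, an antimicrobial peptide, fell from 2839 ± 582 to 0.724 ± 1.02 RPKM (-10.81 ± 1.22, adjusted p = 0.00136) and S100a8 from 8683 ± 2243 to 41.9 ± 0.229 RPKM (-7.64 ± 1.05, adjusted p = 0.00325). 18 of 19 neutrophil genes fell (19 when adjusted over the list alone) and 0 rose. Neutrophil genes gave camera adjusted p = 4.7e-19, and adjusted p = 0.263 with an estimated correlation. Elane, neutrophil elastase, fell from 977 ± 201 to 0.269 ± 0.381 RPKM (-9.61 ± 0.96, adjusted p = 0.000824). Mpo, myeloperoxidase, had 544 ± 137 RPKM at day 4 and no reads at day 7, at least 5060-fold lower against the floor of 3 reads per library (adjusted p = 0.000331). In the myeloid progenitor list 8 of 15 fell and 3 rose, Csf1r among the latter (10 and 3 when adjusted over the list alone). Myeloid progenitor genes gave camera adjusted p = 0.0416, and adjusted p = 0.483 with an estimated correlation, and their call was lost in 10 of 23 alternatives, with adjusted p = 0.117 without day 4 library I and 0.691 without day 4 library II. Basophil and mast genes had 7 of 12 lower (7 when adjusted over the list alone). Basophil and mast cell genes gave camera adjusted p = 3.8e-05, and adjusted p = 0.263 with an estimated correlation. Hdc went from 331 ± 112 RPKM to no reads, at least 2870-fold lower (adjusted p = 0.000106). Eosinophil genes had 2 of 10 lower (5 when adjusted over the list alone). Eosinophil genes gave camera adjusted p = 0.0466, and adjusted p = 0.483 with an estimated correlation, and their call was lost in 12 of 22 alternatives, with adjusted p = 0.0691 under quantile normalization and 0.721 without day 4 library II. Prg2, the major basic protein, went from 177 ± 68.6 to 1.38 ± 1.804 RPKM (-6.41 ± 1.09, adjusted p = 0.00825). Of 22 erythroid genes 13 fell (16 when adjusted over the list alone). Erythroid genes gave camera adjusted p = 9.44e-10, and adjusted p = 0.231 with an estimated correlation. Hbb-b1 went from 1617 ± 91.2 to 5.199 ± 2.49 RPKM (-8.09 ± 0.61, adjusted p = 0.000312).

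Many genes of cell division fell. Mki67, a marker of dividing cells, fell from 31.8 ± 18.5 to 1.56 ± 0.4896 RPKM (-3.57 ± 0.60, adjusted p = 0.00764) and Ccna2, cyclin A2, from 29.97 ± 11.8 to 2.87 ± 0.745 RPKM (-2.96 ± 0.43, adjusted p = 0.00408). 18 of 23 mitosis genes fell (21 when adjusted over the list alone) and 0 rose. Mitosis genes gave camera adjusted p = 1.5e-09, and adjusted p = 0.263 with an estimated correlation. In the S phase list 8 of 20 fell and 1 rose (11 and 1 when adjusted over the list alone). S phase genes gave camera adjusted p = 0.0416, and adjusted p = 0.508 with an estimated correlation, and their call was lost in 11 of 23 alternatives, with adjusted p = 0.0911 without day 0 library II, 0.0904 without day 0 library III and 0.634 without day 4 library II. The one that rose was Pcna, the sliding clamp of DNA synthesis and repair, from 63.3 ± 27.03 to 533 ± 99.4 RPKM (3.11 ± 0.46, adjusted p = 0.00462), while Rrm2, a subunit of ribonucleotide reductase, fell from 82.8 ± 48.7 to 5.07 ± 0.898 RPKM (-3.66 ± 0.47, adjusted p = 0.0024). Cholesterol synthesis had 4 of 20 lower (8 when adjusted over the list alone). Cholesterol synthesis genes gave camera adjusted p = 0.0466, and adjusted p = 0.483 with an estimated correlation, and their call was lost in 9 of 23 alternatives, with adjusted p = 0.634 without day 4 library II. Idi1, of isoprenoid synthesis, went from 36.2 ± 0.475 to 7.09 ± 3.05 RPKM (-2.25 ± 0.47, adjusted p = 0.0187).

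Genes of protein synthesis, respiration and the lysosome were among those that rose. Ribosomal protein genes had 44 of 78 higher and 0 lower (63 and 0 when adjusted over the list alone). Ribosomal protein genes gave camera adjusted p = 4.14e-38, and adjusted p = 0.378 with an estimated correlation, and their call was lost in 2 of 23 alternatives, with adjusted p = 0.0726 by fry. Rplp1 rose from 64.7 ± 22.96 to 2687 ± 405 RPKM (5.39 ± 0.63, adjusted p = 0.00158), and Rpl13 stood at 464 ± 72.98 and 1878 ± 195 RPKM (adjusted p = 0.199), both with pseudogene copies that can share reads. Oxidative phosphorylation had 10 of 23 higher (12 when adjusted over the list alone). Oxidative phosphorylation genes gave camera adjusted p = 3.29e-11, and adjusted p = 0.35 with an estimated correlation. Cox7c, a cytochrome oxidase subunit, went from 37.9 ± 2.83 to 729 ± 125 RPKM (4.22 ± 0.56, adjusted p = 0.00282). 11 of 21 lysosome genes rose (15 rose and 1 fell when adjusted over the list alone). Lysosome genes gave camera adjusted p = 3.29e-11, and adjusted p = 0.263 with an estimated correlation. Npc2, a cholesterol carrier, went from 48.2 ± 10.7 to 623 ± 13.5 RPKM (3.68 ± 0.40, adjusted p = 0.00121). Immediate early genes had 7 of 15 higher and 2 lower (7 and 4 when adjusted over the list alone). Immediate early genes gave camera adjusted p = 0.00226, and adjusted p = 0.501 with an estimated correlation, and their call was lost in 6 of 23 alternatives, with adjusted p = 0.511 under quantile normalization. Fos rose from 44.6 ± 32.5 to 939.9 ± 118 RPKM (4.57 ± 0.58, adjusted p = 0.00229) and Dusp1, a phosphatase of MAP kinases, from 107 ± 60.5 to 1015 ± 90.7 RPKM (3.36 ± 0.54, adjusted p = 0.00621).

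Lists of dendritic cell genes moved in part. The type 1 conventional DC list was called higher (camera adjusted p = 0.0229, or adjusted p = 0.498 with an estimated correlation, the call being lost in 6 of 23 alternatives), with 4 of 16 genes higher and 1 lower (6 and 2 when adjusted over the list alone). Its median log2 fold change of 0.18 ran from -0.96, with members of no other list, to 4.09, with genes of at least 20 RPKM (adjusted p = 0.417 and 0.17). Cd36, a scavenger receptor also known from macrophages, rose from 6.72 ± 0.388 to 456 ± 26.6 RPKM (5.89 ± 0.34, adjusted p = 0.000149) and Id2, an inhibitor of helix-loop-helix factors, from 68.97 ± 25.4 to 1511 ± 104 RPKM (4.48 ± 0.75, adjusted p = 0.00763). Irf8, a transcription factor of DCs and monocytes, rose from 6.14 ± 1.93 to 37.2 ± 2.29 RPKM (2.45 ± 0.38, adjusted p = 0.0058) and Rab7b, of endosomal traffic, from 2.19 ± 0.315 to 53.5 ± 7.84 RPKM (4.09 ± 0.41, adjusted p = 0.00079). Clec9a and Xcr1, surface receptors of type 1 DCs, stood at 1.61 ± 1.08 and 2.77 ± 1.44 RPKM at day 4 and 0.351 ± 0.497 and 0.264 ± 0.374 RPKM at day 7 (adjusted p = 0.4 and 0.15). DC transcription factors had 5 of 26 higher and 3 lower (5 and 4 when adjusted over the list alone). DC transcription factors gave camera adjusted p = 0.00665, and adjusted p = 0.35 with an estimated correlation, and their call was lost in 8 of 23 alternatives, with adjusted p = 0.0665 under quantile normalization. Cebpb, a myeloid factor, rose from 2.28 ± 1.16 to 119.5 ± 35.3 RPKM (5.21 ± 0.58, adjusted p = 0.00134). 3 plasmacytoid DC genes rose and 1 fell of 20 (3 and 1 when adjusted over the list alone). Plasmacytoid DC genes gave camera adjusted p = 0.531, and adjusted p = 0.821 with an estimated correlation. Bst2, also an interferon-induced gene, rose from 19.5 ± 17.04 to 664 ± 70.8 RPKM (5.32 ± 0.99, adjusted p = 0.0117), and Siglech stood at 6.91 ± 5.76 and 6.83 ± 1.97 RPKM (adjusted p = 0.864). Among 29 conventional DC genes 2 rose and 6 fell (3 and 6 when adjusted over the list alone). Conventional DC genes gave camera adjusted p = 0.877, and adjusted p = 0.956 with an estimated correlation. Itgax, which encodes CD11c, was at 4.22 ± 3.08 and 25.3 ± 0.846 RPKM (adjusted p = 0.0805). Limma called 0 of 26 interferon-stimulated genes over all genes and 0 when adjusted over the list alone (2 were higher and 2 lower at unadjusted p under 0.05), while the list was called higher. Interferon-stimulated genes gave camera adjusted p = 0.00967, and adjusted p = 0.663 with an estimated correlation, and their call was lost in 8 of 23 alternatives, with adjusted p = 0.439 under quantile normalization and 0.634 without day 4 library II. Cytokine receptors had 5 of 22 higher and 3 lower (8 and 5 when adjusted over the list alone). Cytokine receptors gave camera adjusted p = 0.0248, and adjusted p = 0.483 with an estimated correlation, and their call was lost in 8 of 23 alternatives, with adjusted p = 0.777 under quantile normalization and 0.0879 without day 4 library I. The list's median log2 fold change of -0.06 lay below 0 while its mean of 0.37 and its test lay above.

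Limma called 1127 genes higher and 1301 lower at day 7 than at day 4 (46.4% higher), against 696 and 1572 (30.7% higher) after scaling to a common total. The split was 2396 and 10392 (18.7% higher) with voom, 1150 and 2846 (28.8%) with a pseudocount of 0.1, 1047 and 764 (57.8%) after background subtraction and 1179 and 836 (58.5%) with genes of at least 20 RPKM. Camera called 11 lists higher and 8 lower, of which 0 passed with an estimated correlation (6 of 34 at unadjusted p under 0.05), a form with little power here. Median or mean and test differed in sign in 7 lists, the cytokine receptors above and the uncalled lists for plasmacytoid, conventional and type 2 conventional DCs, DC maturation, innate sensors and plasma cells. The all-gene median of -0.81 became -1.35, -0.70 and 0.04 after scaling to a common total, to median ratios and to common quantiles. Of the genes named in the text 73 passed in this comparison, and all of these had both libraries of one day above both of the other, as the naming rule required of some. Receptor genes were 41 of the 1301 lower genes and 0 of the higher ones, and the 6 Y-linked genes had 583 and 970 reads in the day 4 libraries and 0 in both day 7 libraries, while the labels give male for all 6 libraries. The receptor share and the loss of Y-linked reads moved with every group described above, and Xist, the X-inactivation RNA of female cells, rose from 0.2402 ± 0.284 to 8.104 ± 2.16 RPKM (2.88 ± 0.58, adjusted p = 0.0162). Without day 4 library I or II limma called 0 genes (4062 and 7160 at unadjusted p under 0.05), without day 0 library II or III 4120 and 4034, without day 7 library III or IV 821 and 622, and after quantile normalization 978. In simulated data with 4000 changed genes 1.98% of the calls fell on unchanged genes, 49 in number, of which 5 were called lower. Changed genes were drawn there only from a mean of at least 5 RPKM, so the share is no error rate for the real calls.

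**Figure D3:**
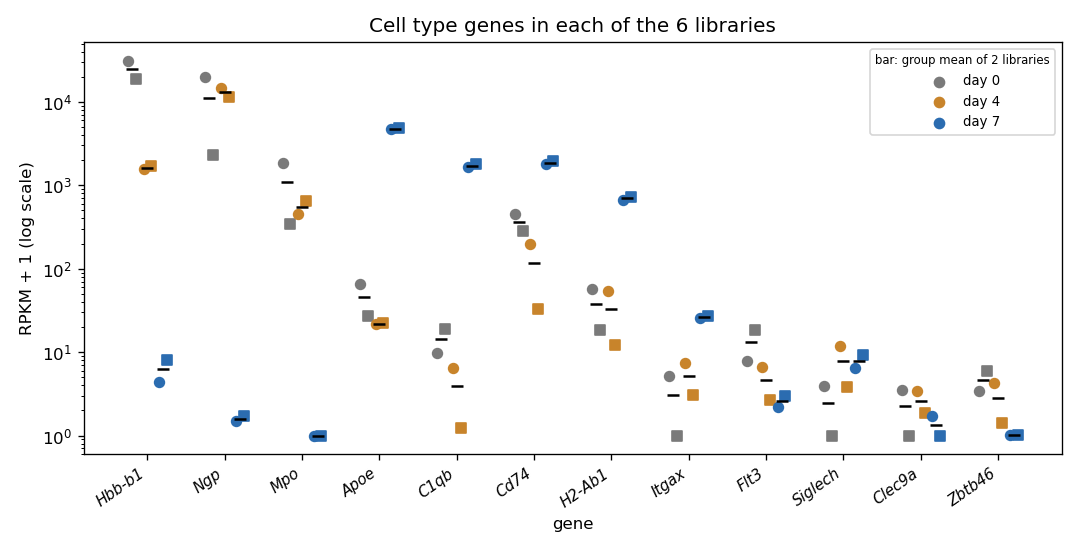
RPKM + 1 (log scale) of 12 cell type genes in each of the 6 libraries, circle and square marking the 2 libraries of a day and bars their group mean. Both day 7 libraries lay above all others for Apoe, C1qb, Cd74 and H2-Ab1 and below all others for Hbb-b1, Ngp and Mpo, and Siglech overlapped between days.

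Day 7 was compared with day 0 to span the whole culture. Among genes with a mean of at least 5 RPKM and reads on both days the largest called falls were those of the globin gene Hbb-bs, from 31505 ± 8622 RPKM at day 0 to 6.199 ± 0.279 RPKM at day 7 (-12.07 ± 0.61, adjusted p = 0.000118), of Ngp, from 11154 ± 12486 to 0.594 ± 0.161 RPKM (-12.07 ± 0.93, adjusted p = 0.000332), and of Hbb-b1, down to 5.199 ± 2.49 RPKM (-11.98 ± 0.61, adjusted p = 0.000118). All 22 erythroid genes fell (22 when adjusted over the list alone). Erythroid genes gave camera adjusted p = 1.99e-14, and adjusted p = 0.122 with an estimated correlation. 18 of 19 neutrophil genes fell (18 when adjusted over the list alone). Neutrophil genes gave camera adjusted p = 1.88e-10, and adjusted p = 0.298 with an estimated correlation. Macrophage genes had 11 of 20 higher and 4 lower (11 and 4 when adjusted over the list alone). Monocyte and macrophage genes gave camera adjusted p = 4.76e-08, and adjusted p = 0.269 with an estimated correlation, and their call was lost in 2 of 23 alternatives, with adjusted p = 0.108 at 20 RPKM. Apoe rose from 44.9 ± 26.6 to 4762 ± 45.9 RPKM (6.83 ± 0.50, adjusted p = 0.000296) and Cd68, a lysosomal glycoprotein of macrophages, from 16.3 ± 1.798 to 2158 ± 209.9 RPKM (6.96 ± 0.47, adjusted p = 0.000209). The largest called rises of genes with reads on both days were those of Fabp5, a fatty acid carrier, from 6.65 ± 9.4 to 1678 ± 177 RPKM (8.79 ± 1.01, adjusted p = 0.00128), and of Gpnmb, a lysosomal membrane protein of macrophages, from 4.12 ± 1.1 to 2191 ± 10.4 RPKM (8.76 ± 0.40, adjusted p = 0.000118). Rpph1, the RNA of RNase P, had no reads at day 0 and 498 ± 343 RPKM at day 7, and so was at least 7.96-fold higher (adjusted p = 0.000156).

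Lysosome genes rose in 20 of 21 cases (20 when adjusted over the list alone). Lysosome genes gave camera adjusted p = 1.24e-20, and adjusted p = 0.23 with an estimated correlation. Ctsd reached 4242 ± 389 RPKM (5.48 ± 0.70, adjusted p = 0.00193). MHC class II had 9 of 14 higher and 1 lower (9 and 2 when adjusted over the list alone). MHC class II genes gave camera adjusted p = 3.41e-07, and adjusted p = 0.396 with an estimated correlation. Cd74 rose from 367 ± 119 to 1873 ± 83.3 RPKM (2.39 ± 0.81, adjusted p = 0.0471). Class I had 5 of 13 higher (6 higher and 1 lower when adjusted over the list alone). MHC class I genes gave camera adjusted p = 0.000431, and adjusted p = 0.233 with an estimated correlation, and their call was lost in 3 of 23 alternatives, with adjusted p = 0.167 under quantile normalization and 0.23 at 20 RPKM. Innate sensors had 4 of 23 higher and 2 lower (4 and 2 when adjusted over the list alone). Innate sensors gave camera adjusted p = 0.00738, and adjusted p = 0.269 with an estimated correlation, and their call was lost in 4 of 23 alternatives, with adjusted p = 0.0986 at 5 RPKM, 0.235 at 20 RPKM and 0.109 by fry. Clec7a, the beta-glucan receptor, rose from 15.2 ± 6.09 to 372 ± 7.57 RPKM (4.58 ± 0.47, adjusted p = 0.000804). Interferon-stimulated genes had 3 of 26 higher and 2 lower (3 and 1 when adjusted over the list alone). Interferon-stimulated genes gave camera adjusted p = 0.000768, and adjusted p = 0.547 with an estimated correlation, and their call was lost in 4 of 23 alternatives, with adjusted p = 0.1 at 5 RPKM, 0.826 at 20 RPKM and 0.46 by fry. Isg15, a ubiquitin-like modifier, had no reads at day 0 and 35.4 ± 5.596 RPKM at day 7, at least 1.41-fold higher (adjusted p = 0.000741), and Rsad2, an antiviral enzyme, fell from 89.3 ± 44.7 to 10.7 ± 4.997 RPKM (-2.93 ± 0.72, adjusted p = 0.019).

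Cytokine receptors had 11 of 22 higher and 5 lower (14 and 6 when adjusted over the list alone). Cytokine receptors gave camera adjusted p = 9.88e-05, and adjusted p = 0.298 with an estimated correlation, and their call was lost in 2 of 23 alternatives, with adjusted p = 0.175 under quantile normalization. Csf1r rose from 14.5 ± 4.01 to 230.4 ± 15.7 RPKM (3.93 ± 0.42, adjusted p = 0.000926). Ribosomal protein genes had 46 of 78 higher (53 when adjusted over the list alone). The list medians differed between the day 0 libraries, at 285 and 70.2 RPKM, against 678 and 683 RPKM at day 7. The median log2 fold change of 2.33 ran from 0.875 to 3.38 over the alternatives. Ribosomal protein genes gave camera adjusted p = 4.29e-25, and adjusted p = 0.405 with an estimated correlation, and their call was lost in 2 of 23 alternatives, with adjusted p = 0.0966 by fry. Oxidative phosphorylation had 16 of 23 higher (16 when adjusted over the list alone). Oxidative phosphorylation genes gave camera adjusted p = 4.83e-12, and adjusted p = 0.298 with an estimated correlation. Glycolysis had 5 of 13 higher and 1 lower (5 and 1 when adjusted over the list alone). Glycolysis genes gave camera adjusted p = 0.000641, and adjusted p = 0.405 with an estimated correlation, and their call was lost in 5 of 23 alternatives, with adjusted p = 0.611 under quantile normalization. Among p53 targets 6 of 12 rose and 1 fell (6 and 1 when adjusted over the list alone). Targets of p53 gave camera adjusted p = 6.86e-05, and adjusted p = 0.23 with an estimated correlation, and their call was lost in 2 of 23 alternatives, with adjusted p = 0.348 at 20 RPKM. Cdkn1a rose from 4.16 ± 4.24 to 169 ± 2.66 RPKM (5.34 ± 0.59, adjusted p = 0.0011). Mitosis genes fell in 20 of 23 cases (20 when adjusted over the list alone). Mitosis genes gave camera adjusted p = 3.57e-07, and adjusted p = 0.288 with an estimated correlation. S phase had 14 of 20 lower and 1 higher (15 and 1 when adjusted over the list alone). S phase genes gave camera adjusted p = 0.000641, and adjusted p = 0.396 with an estimated correlation. B lineage genes had 13 of 19 lower and 1 higher (14 and 1 when adjusted over the list alone). The list medians at day 0, 5.24 and 6.07 RPKM, lay under the floors of 3 reads of a 1 kb gene, 9.29 and 19.01 RPKM. The median log2 fold change was -2.43 for the list and -1.898 for the tested receptor genes. B lineage genes gave camera adjusted p = 0.035, and adjusted p = 0.545 with an estimated correlation, and their call was lost in 7 of 22 alternatives, with adjusted p = 0.0522 under quantile normalization and 0.0912 without day 0 library II. Cd79a, a B cell receptor subunit, fell from 14.1 ± 13.1 to 1.22 ± 0.849 RPKM (-2.47 ± 0.71, adjusted p = 0.0284), and Blnk, an adaptor also found in myeloid cells, rose from 5.79 ± 0.0929 to 40.2 ± 3.19 RPKM (2.60 ± 0.44, adjusted p = 0.00581). Basophil and mast genes had 6 of 12 lower (7 when adjusted over the list alone). Basophil and mast cell genes gave camera adjusted p = 0.0107, and adjusted p = 0.288 with an estimated correlation, and their call was lost in 2 of 22 alternatives, with adjusted p = 0.057 without day 0 library II. The immediate early list was called higher (camera adjusted p = 0.0202, or adjusted p = 0.552 with an estimated correlation, the call being lost in 7 of 23 alternatives, with adjusted p = 0.18 under quantile normalization and 0.057 without day 0 library II) with 6 of 15 higher and 2 lower (6 and 2 when adjusted over the list alone), a median log2 fold change of -0.53 and a mean of 0.57, and under quantile normalization its test turned lower with a median of -0.99 (adjusted p = 0.18).

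Dendritic cell genes again went both ways, while 435 of 1020 tested receptor genes fell with a median log2 fold change of -1.898. Itgax rose from 2.08 ± 2.94 to 25.3 ± 0.846 RPKM (3.53 ± 0.79, adjusted p = 0.0148) and Sirpa, a surface protein of type 2 DCs and macrophages, from 53.95 ± 26.2 to 273 ± 1.71 RPKM (2.40 ± 0.47, adjusted p = 0.00937). Flt3 fell from 12.1 ± 7.46 to 1.596 ± 0.533 RPKM (-2.22 ± 0.65, adjusted p = 0.0303) and Xcr1 from 5.297 ± 2.57 to 0.264 ± 0.374 RPKM (-2.29 ± 0.63, adjusted p = 0.0259). Zbtb46 fell from 3.65 ± 1.77 to 0.0285 ± 0.000345 RPKM (-2.12 ± 0.72, adjusted p = 0.0462), against 0.08 under quantile normalization (adjusted p = 0.914). Plasmacytoid DC genes had 3 of 20 higher and 7 lower (4 and 8 when adjusted over the list alone). Plasmacytoid DC genes gave camera adjusted p = 0.604, and adjusted p = 0.829 with an estimated correlation. Conventional DC genes had 3 of 29 higher and 10 lower (3 and 10 when adjusted over the list alone). Conventional DC genes gave camera adjusted p = 0.521, and adjusted p = 0.829 with an estimated correlation. The type 1 list had 5 of 16 higher and 6 lower (5 and 6 when adjusted over the list alone). Type 1 conventional DC genes gave camera adjusted p = 0.347, and adjusted p = 0.721 with an estimated correlation. The type 2 list had 3 of 14 higher and 4 lower (3 and 5 when adjusted over the list alone). Type 2 conventional DC genes gave camera adjusted p = 0.335, and adjusted p = 0.552 with an estimated correlation. DC maturation genes, of co-stimulation and migration, had 4 of 20 higher and 3 lower (4 and 1 when adjusted over the list alone). DC maturation genes gave camera adjusted p = 0.0736, and adjusted p = 0.468 with an estimated correlation. Pooled receptor genes stood at 8.71 and 8.29 RPKM in the day 0 libraries, above the day 0 means of Xcr1 and Zbtb46. The median receptor gene, at 3.11 and 2.47 RPKM there, lay below those means. The conventional DC list had a median log2 fold change of -1.24. In both day 7 libraries the medians of the plasmacytoid, conventional and type 1 conventional DC lists were at most 1.44% of the monocyte and macrophage median. That of the type 2 list was at most 1.83%, and those of the maturation and transcription factor lists at most 2.3% and 4.23%. The MHC class II medians, 176 and 202 RPKM, lay near the monocyte and macrophage medians, 185 and 206 RPKM.

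Limma called 2183 genes higher and 5649 lower at day 7 than at day 0 (27.9% higher), against 1211 and 930 (56.6% higher) under quantile normalization. The split was 1333 and 10155 (11.6% higher) with voom, 2373 and 1724 (57.9%) after background subtraction, 2189 and 2768 (44.2%) at 5 RPKM and 1863 and 560 (76.9%) at 20 RPKM. Camera called 12 lists higher and 6 lower, of which 0 passed with an estimated correlation (6 of 34 at unadjusted p under 0.05), a form with little power here. Median or mean and test differed in sign in 7 lists, the immediate early list above and the uncalled lists for plasmacytoid, type 1 and type 2 conventional DCs, DC transcription factors, plasma cells and megakaryocytes. The all-gene median of -1.14 became -1.63, -0.96 and -0.01 after scaling to a common total, to median ratios and to common quantiles. Of the genes named in the text 87 passed in this comparison, and all of these had both libraries of one day above both of the other, as the naming rule required of some. Receptor genes, 435 of 1020 tested, were 7.70% of the lower genes and 0 of the higher ones, and the 6 Y-linked genes had 42 and 30 reads at day 0 and 0 at day 7. The fall of both moved with every gene group of this comparison, and Xist stood at 9.63 and 6.58 RPKM in the day 7 libraries against 1.24 and 2.23 RPKM in the day 0 libraries. Without day 7 library III or IV limma called 1455 and 1173 genes (54.7% and 57.0% higher), and with genes of at least 5 RPKM or 20 RPKM in 2 libraries 4957 and 2423. In simulated data with 4000 changed genes 33.0% of the calls fell on unchanged genes, 1347 in number. Of these 50 were called lower and the others higher, and 146 had a mean of at least 5 RPKM. Changed genes were drawn only from that mean upward, so every call below it fell on an unchanged gene. The share is therefore no error rate for the real calls. With 200 changed genes the share was 38.8%, and 17 of the unchanged genes called had a mean of at least 5 RPKM.

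Genes called in both steps but in opposite directions were taken as highest or lowest at day 4. Among the highest, Prss34 fell from 336 ± 146 to 0.586 ± 0.828 RPKM by day 7 (-7.76 ± 1.33, adjusted p = 0.00847), and Ifit1bl2, of the IFIT family, stood at 6.92 ± 7.13, 249 ± 34.1 and 0.3202 ± 0.146 RPKM on the 3 days. Fpr1, the formyl peptide receptor of neutrophils, stood at 12.98 ± 4.81, 529 ± 161 and 11.98 ± 0.725 RPKM and Slc7a11 at 4.85 ± 0.511, 291 ± 201 and 7.69 ± 0.0488 RPKM. The adjusted p for Fpr1 was 0.00544 for the rise and 0.000325 for the fall. The lowest included Cebpb at 52.4 ± 39.1, 2.28 ± 1.16 and 119.5 ± 35.3 RPKM and Ybx3, a cold-shock protein, at 42.1 ± 3.05, 2.88 ± 0.926 and 62.1 ± 4.87 RPKM. Crip1, a small zinc-binding protein, stood at 87.3 ± 43.2, 9.11 ± 7.96 and 1171 ± 224 RPKM, Mgst3, a glutathione transferase, at 61.5 ± 16.5, 5.503 ± 2.002 and 241 ± 38.4 RPKM, and Fosb at 18.2 ± 6.71, 1.01 ± 0.431 and 175 ± 10.8 RPKM. For Cebpb the adjusted p was 0.0152 for the fall and 0.00134 for the rise. In all, 267 genes were highest at day 4, against 47.6 for independent lists, and 55 were lowest, against 21.6, while 51 rose at both steps (41.2 for independent lists) and 38 fell at both (24.97). Both steps share the day 4 libraries. In 20 draws of unchanged simulated groups limma called a median of 0.5 and 0 genes in the 2 steps. The same numbers of genes taken from each draw by smallest p gave a median of 252.5 highest and 107 lowest at day 4 (at most 271 and 119), and 18 higher and 6 lower at both steps (at most 27 and 8). The counts of 267 and 55 did not exceed the highest of these draws, while those of 51 and 38 did. The draws hold no changed genes, and few of the genes taken from them were called, unlike the genes counted. The comparison therefore neither accounts for 267 and 55 nor backs 51 and 38. Without either day 4 library limma called 0 such genes, without day 0 library II or III 650 and 597, and without day 7 library III or IV 100 and 89.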

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

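Voom on recovered reads, background subtraction, thinning to the smallest library and the filter of 20 RPKM were chosen after seeing the data. Over all alternatives, of values for named genes 6255 kept their side of the threshold, 655 lost it and 144 gained it, while 103 changed sign, all but 2 of them uncalled both as reported and under the alternative. Of list medians 2042 kept their list's side of the threshold (94 of them changed sign), 193 lost it and 72 gained it (13 of the others changed sign), and in 6 the list turned direction by camera. For day 4 against day 0, limma's 1075 genes became 535 with a pseudocount of 0.1, 529 with only the groups compared, 249 without a trend, 0 with weights per library (2757 at unadjusted p under 0.05; weights 0.399, 0.479 and 5.24 by day), 309 with voom, 1763 after background subtraction and 1658 after thinning (449 higher, 1209 lower). The 2428 genes for day 7 against day 4 became 3996 with a pseudocount of 0.1, 978 under quantiles, 3921 with only the groups compared, 1609 without a trend, 12788 with voom and 794 after thinning. The 7832 genes for day 7 against day 0 became 4957 at 5 RPKM, 2141 under quantiles, 4097 after background subtraction, 3274 after thinning and 2423 at 20 RPKM. The 322 genes highest or lowest at day 4 became 182 with a pseudocount of 0.1, 486 at 5 RPKM, 206 under quantiles, 63 without a trend, 0 with weights per library by limma, 98 with voom, 211 after thinning and 496 at 20 RPKM. Leaving out 1 library gave 0 to 2397, 0 to 4120, 1173 to 9200 and 0 to 650 genes in that order, with the lone sample assumed to vary like the other groups; the 0 came without day 4 library I (6499 and 4062 genes at unadjusted p under 0.05) or II (3437 and 7160). Lists called for day 4 against day 0, 12, became 0 with an estimated correlation and 4 with fry. For day 7 against day 4, 19 became 0 with an estimated correlation and 15 with fry. They became 11 after background subtraction, after thinning and at 20 RPKM. For day 7 against day 0, 18 became 0 with an estimated correlation, 19 with fry and 11 at 20 RPKM. Direction turned for Gapdh at day 7 against day 0 (-0.43, or -2.34 to 1.48 leaving out 1 library, the highest without day 0 library II) and Zbtb46 there (-2.12, or 0.084 under quantiles). By camera it turned for the immediate early list there (median -0.986 under quantiles, 0.084 at 20 RPKM) and for the oxidative phosphorylation list at day 4 against day 0 (0.169 under quantiles, 0.521 at 20 RPKM, and -0.072 to 0.955 leaving out 1 library, the lowest without day 0 library III). The ribosomal list there went from -0.43 to between -1.501, without day 0 library III, and 0.50, without day 0 library II, where its direction turned. No paired analysis was possible because groups share at most 1 replicate numeral. The numeral as a random effect (replicate block, consensus correlation 0.304) gave 1966, 2700 and 9692 genes in the 3 comparisons and 524 highest or lowest at day 4, and deviations of same-numbered libraries correlated at 0.013 and 0.021. Robust eBayes, the replicate block and the log2 threshold of 1 were not run for lists. Fewer genes entered the stricter filters and fewer reads the thinned libraries; elsewhere the cause was not tested. Depth limits day 0 most, where 3 reads of a gene 1 kb long are worth 9.29 and 19.01 RPKM.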

Other observations

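All tests of explanations in this part were chosen after the result was seen, except the test of receptor reads against gene length and that of the share of macrophage genes that rose. From day 4 to day 7 members of the stromal and endothelial list went both ways. Fabp4, a fatty acid carrier also found in macrophages, went from 1.18 ± 0.0512 to 439 ± 43.2 RPKM (7.65 ± 0.73, adjusted p = 0.000687 by limma) and Lpl, lipoprotein lipase, from 7.81 ± 0.204 to 733 ± 98.8 RPKM (6.38 ± 0.35, adjusted p = 0.000136), while Vcam1, an adhesion molecule, fell from 18.3 ± 3.305 to 0.697 ± 0.367 RPKM (-3.52 ± 0.45, adjusted p = 0.0025). Of 16 tested members 3 rose and 3 fell (3 and 4 when adjusted over the list alone). Stromal and endothelial genes gave camera adjusted p = 0.784, and adjusted p = 0.897 with an estimated correlation. In the DNA methylation list 1 of 10 rose and 3 fell (2 and 3 when adjusted over the list alone). DNA methylation genes gave camera adjusted p = 0.555, and adjusted p = 0.722 with an estimated correlation. Dnmt1, the maintenance methyltransferase, fell from 49.02 ± 28.9 to 4.82 ± 1.51 RPKM (-2.996 ± 0.49, adjusted p = 0.00721) and Uhrf1, its cofactor, from 15.9 ± 1.76 to 3.72 ± 0.628 RPKM (-1.85 ± 0.36, adjusted p = 0.015). Nuclear architecture had 1 of 17 higher and 2 lower (1 and 6 when adjusted over the list alone). Nuclear architecture genes gave camera adjusted p = 0.209, and adjusted p = 0.509 with an estimated correlation. By fry, which does not set a list against other genes, the members fell on balance (adjusted p = 0.0325). Lmna, which encodes lamins A and C, rose from 5.28 ± 0.706 to 78.9 ± 15.9 RPKM (3.66 ± 0.38, adjusted p = 0.000986), and Lbr, the lamin B receptor, fell from 175 ± 13.7 to 8.84 ± 2.31 RPKM (-4.18 ± 0.38, adjusted p = 0.000565).

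From day 0 to day 7, 12 of 21 stem and early progenitor genes fell and 3 rose (14 and 3 when adjusted over the list alone). Stem and early progenitor genes gave camera adjusted p = 0.136, and adjusted p = 0.405 with an estimated correlation. By fry, which does not set a list against other genes, the members fell on balance (adjusted p = 0.00307). Kit, the stem cell factor receptor, fell from 15.8 ± 7.36 to 0.0458 ± 0.00665 RPKM (-3.94 ± 0.56, adjusted p = 0.00292 by limma), and Cd34, a progenitor surface protein, fell from 8.67 ± 1.25 to 2.38 ± 0.0233 RPKM (-1.51 ± 0.48, adjusted p = 0.0375). Of 1020 tested receptor genes 435 fell as well, and pooled they stood at 8.71 and 8.29 RPKM at day 0. T and NK genes had 6 of 18 lower and 2 higher (9 and 2 when adjusted over the list alone). T and NK cell genes gave camera adjusted p = 0.307, and adjusted p = 0.753 with an estimated correlation. Plasma cell genes had 2 of 6 higher and 2 lower (2 and 2 when adjusted over the list alone). Plasma cell genes gave camera adjusted p = 0.347, and adjusted p = 0.638 with an estimated correlation. Megakaryocyte genes had 1 of 14 higher and 2 lower (1 and 2 when adjusted over the list alone). Megakaryocyte genes gave camera adjusted p = 0.728, and adjusted p = 0.889 with an estimated correlation.

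Genes of sensory receptors took 1.51% and 1.44% of reads at day 0 and under 0.01% at day 7. Counting noise at low depth is argued against, since the lower exact bound of the share in the smallest library was 1.377%. A few receptor genes cannot have been the only source, since 865 and 746 of 1449 had reads at day 0 and 1324 and 1071 at day 4. Transcription of a few as a part of the source stays open. The 10 with most reads held 66.77% and 47.86% of receptor reads at day 0 and 32.07% and 33.12% at day 4. Reads spread over gene sequence regardless of transcription may be a source, since reads per receptor gene rose with length at a Spearman rho of at least 0.202 in these 4 libraries, but cannot be told apart from other sources, since the day 7 libraries gave 0.142 and 0.105 too. Depth and day change together, and no other biological explanation was tested.

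The 6 Y-linked genes together had reads in all day 0 and day 4 libraries and 0 in both day 7 libraries, and Xist had 9.63 and 6.575 RPKM at day 7 against at most 2.23 RPKM elsewhere. Low depth is argued against, since 3 reads of Ddx3y were worth 0.05818 RPKM at day 7 and Ddx3y stood at 46.8 and 31.8 RPKM at day 4. Background as the source of Y-linked reads at day 4 is argued against, since pooled Y-linked RPKM was 3.004 and 9.06 times that of receptor genes there. At day 0 it was only 0.455 and 0.698 times, but 10 receptor genes held 66.77% and 47.86% of receptor reads there. Day 7 cells from female animals, or labels that give the wrong sex, remain a candidate explanation that the data fit, and the sex of the animals then changes together with the day. The labels give no other source for these cells.

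Macrophage genes stood above DC genes at day 7, with macrophage list medians of 185 and 206 RPKM against at most 8.51 RPKM over 6 DC lists. The MHC class II list, not among the 6, had medians of 176 and 202 RPKM. Medians of different gene lists can differ within any cell type, and no reference population of DCs or macrophages was measured. The macrophage list medians argue against a few abundant genes as the source, since a list median does not rest on a few genes. The 60% of the list's tested members that rose from day 4 passed the share set beforehand against that source. That test adds nothing, because the medians already settle the point. A rise of plasmacytoid, conventional and type 1 conventional DC genes hidden by background stays open, since the measures of background differ. The highest median of these lists at day 7 was 2.657 RPKM. Pooled receptor genes stood at 8.71 and 8.29 RPKM in the day 0 libraries and at 4.33 and 0.846 RPKM in day 4 libraries I and II. The median receptor gene, a measure of the same kind as a list median, stood at 3.11 and 2.47 RPKM at day 0 and 2.28 and 0.279 RPKM at day 4. By the median only day 0 library II lay above 2.657 RPKM. Cells of the macrophage lineage in the culture may account for the pattern, as a hypothesis from the same data, with Cd68 at 2158 ± 209.9 RPKM, Csf1r at 230.4 ± 15.7 RPKM and Flt3 at 1.596 ± 0.533 RPKM, but Itgax at 25.3 ± 0.846, Irf8 at 37.2 ± 2.29 and H2-Ab1 at 698 ± 45.3 RPKM are also genes of DCs, and Ly6c2 of the macrophage list fell to 48.3 ± 1.61 RPKM. Of the 20 macrophage genes 0 are in the plasmacytoid, conventional or type 1 DC lists and 1 is in another list. In both day 0 libraries 17 stood above 1 RPKM, but a single read of a 1 kb gene was worth 3.10 and 6.34 RPKM there. Passing 1 RPKM thus does not show expression at day 0. Expression of these genes in DCs was not tested.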
